A study of Mus musculus with 4 samples.

How the data were processed

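Bulk sequencing measured messenger RNA in whole liver of 4 mouse libraries, 2 from mice fed ethanol alone and 2 from mice fed ethanol and given a binge by gavage. Each library was put in its group by its title, since the treatment protocol in the labels reads the same for all 4 samples. Sex, a control gavage and the time at which the mice without a binge were killed are not given in the sources used here. Per the labels, RNA was extracted with Trizol and libraries were sequenced on a HiSeq2500. Both a TruSeq and a KAPA library kit are named.

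The deposited values are whole-number counts per gene symbol, not normalised, with 1 column per library. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.6.0a, HTSeq, edgeR and the build GRCm38, without saying which step each served. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so reads of near-identical gene copies and of overlapping or antisense genes could have been split, lost or joined. The table holds 22155 symbols, of which 5101 had no count in any library. Totals were 28791281 and 30347558 counts for ethanol alone and 29914491 and 30039731 for the gavage group. A floor of 3 counts corresponds to 0.110, 0.0991, 0.0955 and 0.0996 CPM in replicates 1 and 2 of ethanol alone and replicates 1 and 2 of the gavage group. Floors and the limit given for Y-linked counts cover counting error only, and the bootstrap interval of a correlation covers the spread over genes.

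Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (minimum count 10, minimum total count 15), which left 13309 genes. TMM factors were 0.951 and 0.998 for ethanol alone and 1.05 and 1.00 for the gavage group, and CPM were computed on the TMM-scaled library sizes. The comparison used the 2-sided quasi-likelihood F-test of gavage against ethanol alone with no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 fold changes come from that fit. The SE given is the absolute log2 fold change divided by the square root of the F statistic, not an SE reported by the fit. The common dispersion was 0.0966, a coefficient of variation of 0.311. The 2 libraries of each group were compared before averaging, and chi-square per degree of freedom was 147 for ethanol alone and 157 for the gavage group, so neither pair agreed within sampling noise.

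The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule named the 8 genes with the largest change each way among those past the threshold, with a mean of at least 1 CPM and no overlap of the groups. As none passed, it named the 8 each way with the smallest p under the same conditions on CPM and overlap. Gm and Rik models, pseudogenes and immunoglobulin or T cell receptor segments were left out of this choice. The rule also named the member with the highest mean CPM of each list without a called member, and Cyp2e1, Adh1, Aldh2, Lcn2, Cyp7a1, Fgf21, Srebf1, Cpt1a and Nfil3. Some genes that this rule takes in are not reported here. Other genes were chosen after their values were seen and are said to be so. Of 38 lists of pathway genes and cell type markers, 36 had at least 3 tested members. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 36 lists, and again with a correlation estimated from the residuals and with fry, whose directional p asks whether the genes of a list move, on balance, one way, and whose mixed p asks whether they change in either direction. Members of a list were also counted as called when adjusted over the list alone. Such counts are not adjusted over the lists, and a gene in several lists counts in each. They came to 77, while 0 genes passed over all genes, of which 2497 of 13309 had an unadjusted p under 0.05 in the quasi-likelihood test. Lists of skeletal muscle, male-type and female-type liver, Y-linked and X-linked genes, serine and folate enzymes and the growth hormone axis were added after the data had been seen.

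Coordinates, transcript lengths and GC content came from the GENCODE annotation of GRCm38, matched by symbol, which gave a length for 98.5% of the tested genes. Coordinates span the whole gene, with introns and UTRs. Alternatives changed 1 choice at a time: a replicate block, DESeq2 1.42.0 size factors, upper-quartile factors or library totals in place of TMM, no filter on low counts, a stricter filter (1 CPM in at least 2 libraries), DESeq2, limma-voom or edgeR's likelihood-ratio test in place of the quasi-likelihood test, and each library left out in turn. Chosen after seeing the data were an offset removing the loess trend (span 0.5) in length and GC content, the same offset with the block, with DESeq2 or without replicate 1 of ethanol alone, robust and bias-adjusted quasi-likelihood fits, DESeq2 without each library, and a test without markers of other tissues and sex-biased genes. An adjusted p that DESeq2 did not give was left out of its counts.

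The steps were tested on simulated counts with the real means and library sizes, over 13131 genes with changed genes planted for this comparison. The quasi-likelihood test called 6.12% of genes changed 2-fold, 74% of those changed 4-fold, 88% of those changed 8-fold and 98% of those changed 16-fold, with 15 false calls. False calls numbered 57 for the likelihood-ratio test, 50 for DESeq2 and 15 for limma-voom. Genes were drawn independently and without a difference between replicate numbers, unlike the real libraries. These rates therefore need not hold for the real data. There the quasi-likelihood test called 0 genes, and Gnat1 at 18.0-fold and Psat1 at 17.7-fold were not called. With 2 of 36 lists planted, camera called both with the preset correlation and 0 of them with an estimated correlation, and fry called 0. A planted length trend with a rank correlation of 0.468 was reduced to 0.00752 by the offset.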

Results

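Messenger RNA was measured by sequencing in whole liver of C57BL/6 wild-type mice aged 8 to 10 weeks, an inbred laboratory strain. The mice received a liquid diet with 5% ethanol for 10 days, and 1 group also received a single binge of ethanol at 5 g per kg body weight by gavage, delivery into the stomach through a tube, 9 h before the liver was taken. Each group held 2 libraries, and the comparison asks how gene expression in ethanol-fed liver differs with and without the binge. The total count was 28791281 and 30347558 in the libraries of ethanol feeding alone and 29914491 and 30039731 in those with the gavage. Values below are CPM, counts scaled by library size, as mean ± SD with n = 2 per group. In each pair of group values the gavage group comes first, and fold changes are gavage over ethanol alone. Lists of 3 or 4 libraries run from ethanol alone to the gavage group, by replicate number. The labels do not say that the 2 libraries of a group came from separate animals, so p-values measure only the spread between these samples.

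After the gavage, Lcn2, the iron-binding acute-phase protein lipocalin 2, stood at 414 ± 28.1 against 10.2 ± 4.42 CPM with ethanol feeding alone, a log2 fold change of 5.34 (SE 0.41). Nrg4, a secreted ligand of the epidermal growth factor family, stood at 55.4 ± 6.11 against 5.19 ± 0.557 CPM. Psat1, an enzyme of serine synthesis, stood at 19.9 ± 0.532 against 1.12 ± 0.287 CPM. Gnat1, a transducin subunit, stood at 27.7 ± 1.17 against 1.54 ± 0.357 CPM. Bco2, a carotenoid-cleaving enzyme, lay lower, at 9.97 ± 0.228 against 31.8 ± 3.76 CPM. So did Kcnk5, a potassium channel, at 12.2 ± 0.963 against 55.7 ± 9.81 CPM. No single gene passed the main test. With edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 13309 genes were called and the smallest adjusted p was 0.0638, with 2497 genes at an unadjusted p under 0.05. limma-voom called 0 genes and edgeR's likelihood-ratio test 549 (285 higher and 264 lower). DESeq2 called 1177 (525 higher and 652 lower), of which 523 were shared with the likelihood-ratio test on the same libraries. In simulated counts DESeq2 gave 50 false calls and the likelihood-ratio test 57, against 15 for the quasi-likelihood test. The count of 0 became 12 without replicate 2 of ethanol alone and 31 without replicate 2 of the gavage group.

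Among genes without overlap of the groups, the 8 with the smallest p in each direction failed the adjusted threshold in edgeR's quasi-likelihood test. DESeq2 and edgeR's likelihood-ratio test each called all 16. As the genes were chosen for small p in the same libraries, this adds no separate support for them. Those higher after gavage were Nrg4 (chromosome 9, 55220222 to 55326844; log2 fold change 3.41, SE 0.19, adjusted p = 0.0638) and Gnat1 (chromosome 9, 107674474 to 107679712; 4.17, SE 0.25). They also included Psat1 (chromosome 19, 15904678 to 15947337; 4.15, SE 0.27) and Lcn2 (chromosome 2, 32384633 to 32388252; adjusted p = 0.0675), in GRCm38 coordinates of the whole gene. Cyb5r1 (chromosome 1, 134405559 to 134411740) stood at 36.7 ± 5.05 against 7.99 ± 0.654 CPM and Syt12 (chromosome 19, 4445908 to 4477447) at 11.3 ± 2.5 against 1.02 ± 0.147 CPM. Ddhd2 (chromosome 8, 25725346 to 25754596) stood at 62.7 ± 0.329 against 17.8 ± 0.114 CPM and Lrrc28 (chromosome 7, 67513410 to 67645268) at 151 ± 28.7 against 23.1 ± 3.58 CPM. Those lower were Nxpe2 (chromosome 9, 48318006 to 48353454), at 8.39 ± 0.0202 against 34.3 ± 1.5 CPM, and Arhgef37 (chromosome 18, 61491657 to 61536594), at 2.01 ± 0.0779 against 12.7 ± 0.353 CPM. Kcnk5 (chromosome 14, 20140057 to 20181809) had a log2 fold change of -2.19 (SE 0.20). Pde9a (chromosome 17, 31386210 to 31476310), a cyclic GMP phosphodiesterase, stood at 9.52 ± 0.222 against 28 ± 0.672 CPM and Agfg2 (chromosome 5, 137650463 to 137684726) at 14.7 ± 2.39 against 51.7 ± 2.03 CPM. BC029214, whose symbol was not matched in the annotation used, stood at 7.35 ± 0.173 against 32.7 ± 3.23 CPM. Bco2 (chromosome 9, 50533087 to 50555181) had a log2 fold change of -1.67 (SE 0.17, adjusted p = 0.0927). The libraries of the groups did not overlap for 54.7% of the tested genes, where independent genes would give 33.3% by chance. Genes are not independent and the 4 libraries make only 3 splits, so this share does not test the gavage.

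**Figure D1:**
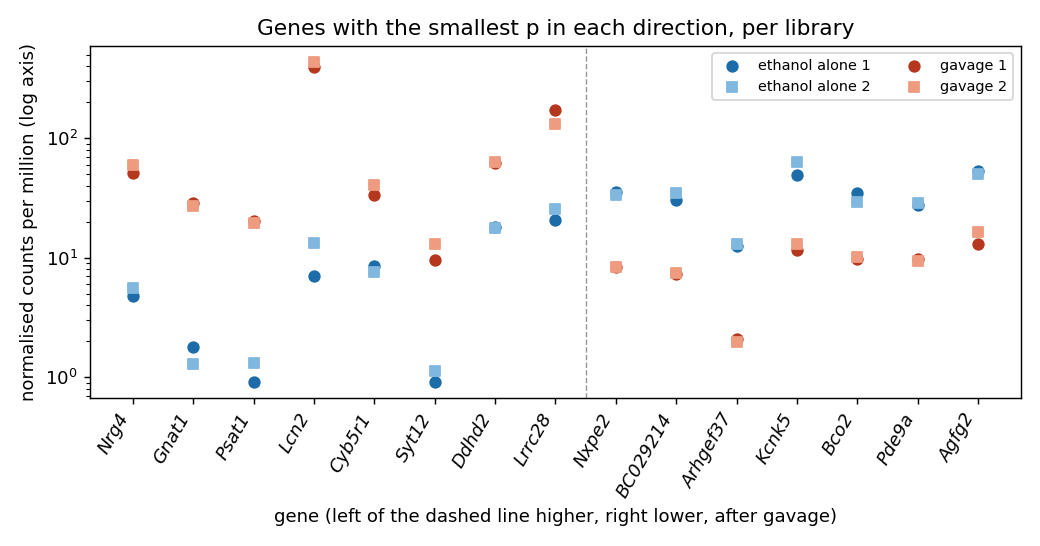
CPM on a log axis for the named genes with the smallest p in each direction, one point per library (circles replicate 1, squares replicate 2; blue ethanol alone, red gavage). Both gavage libraries lie beyond both libraries of ethanol alone for each gene shown, as the rule for naming required, with Lcn2 at 395 and 434 against 7.07 and 13.3 CPM.

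The acute-phase list, plasma proteins and receptors of the hepatic inflammatory response, shifted up after gavage, with 22 of 27 tested members higher and a median log2 fold change of 0.94 (camera with a preset correlation, adjusted p = 1.02e-11). Its adjusted p was 0.587 with an estimated correlation. Fga, a fibrinogen chain and the most abundant member, stood at 14444 ± 1290.0 against 5955 ± 1273 CPM. Members singled out after their values were seen were Serpina3n, at 2388 ± 836 against 367 ± 46.9 CPM, and Orm2, at 47.5 ± 22.7 against 9.31 ± 2.3 CPM. Also singled out was Stat3, the transcription factor, at 259.8 ± 13.1 against 118 ± 3.21 CPM. Over all genes, edgeR's quasi-likelihood test called 0 members, with 17 higher and 2 lower at an unadjusted p under 0.05, and DESeq2 called 16 higher and 1 lower. The quasi-likelihood test called 16 higher and 2 lower adjusted over the list alone. Saa1 differed between the gavage libraries, at 2243 and 304 CPM against 17.6 and 28.7 CPM. Saa1, Saa2 and the Orm genes have near-identical copies whose reads the counting could split. The immediate-early genes, transcription factors and feedback genes of acute signalling, also shifted up (12 of 15 higher, median 0.89, adjusted p = 3.96e-04). With an estimated correlation, the adjusted p was 0.587. Egr1 stood at 206 ± 18.2 against 35 ± 27.6 CPM. Fos and Dusp1 were singled out after their values were seen. Fos stood at 8.93 ± 3.67 against 1.46 ± 0.0909 CPM and Dusp1, a phosphatase of MAP kinases, at 11 ± 2.73 against 50.5 ± 21.9 CPM. Of the immediate-early genes, 7 higher and 1 lower were called adjusted over the list alone. The gene list of the NRF2 and glutathione response, an antioxidant programme, shifted up with 9 of 16 members higher (median 0.27, adjusted p = 0.013). An estimated correlation gave an adjusted p of 0.791. Its leading members, the metal-binding metallothioneins Mt1, at 655 ± 17.1 against 65.8 ± 30.6 CPM, and Mt2, at 346 ± 23.1 against 23.7 ± 12.6 CPM, were singled out after their values were seen. Its most abundant member Gstm1 stood at 729.9 ± 254 against 1083 ± 454 CPM, and 3 members higher and 0 lower were called adjusted over the list alone. Without replicate 1 of ethanol alone the adjusted p of that list was 0.424, and it was 0.121 without genes that also stand in another list.

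The heat shock list, chaperones of protein folding, shifted down after gavage, with 12 of 12 tested members lower (median -0.83, adjusted p = 8.16e-07). Its adjusted p was 0.587 with an estimated correlation. Hspa8, its most abundant member, stood at 148 ± 21 against 239 ± 52 CPM. Dnajb1, at 19.4 ± 3.49 against 43.1 ± 0.453 CPM, and Hsph1, at 40.6 ± 7.37 against 149 ± 71.7 CPM, were singled out after their values were seen. So was Hspa1b, which has a near-identical copy, at 4.36 ± 0.721 against 25.3 ± 18 CPM. The quasi-likelihood test called 0 members higher and 6 lower adjusted over the list alone. Over all genes it called 0, with 0 higher and 8 lower at an unadjusted p under 0.05, while DESeq2 called 0 higher and 4 lower. Markers of Kupffer cells and macrophages, the resident phagocytes of the liver, shifted down with 12 of 13 lower (median -0.69, adjusted p = 1.67e-05). With an estimated correlation, the adjusted p was 0.587. Cd5l stood at 109.7 ± 10.6 against 177 ± 6.19 CPM and Folr2, singled out after its value was seen, at 7.64 ± 0.0482 against 17.7 ± 1.26 CPM, and 0 members higher and 7 lower were called adjusted over the list alone. Neutrophil markers shifted up, with 6 of 6 tested members higher (median 1.82, adjusted p = 0.013). Of the 16 neutrophil markers in the file, only these 6 were tested. The estimated correlation between them was 0.911, but on 2 residual degrees of freedom it is uncertain, and the 6 cannot be taken as independent. With that estimate their adjusted p was 0.791. S100a9, the most abundant, stood at 4.96 ± 4.2 against 1.26 ± 0.189 CPM, with 0 higher and 0 lower called adjusted over the list alone. Without replicate 1 of the gavage group the adjusted p of the neutrophil list was 0.152, and with the stricter filter on low counts it was 0.0683. Interferon-stimulated genes shifted down with 15 of 20 lower (median -0.42, adjusted p = 0.0263). An estimated correlation gave an adjusted p of 0.791. Iigp1, an interferon-inducible GTPase, stood at 283 ± 62.4 against 427 ± 96.6 CPM. Bst2, singled out after its value was seen, stood at 56.4 ± 5.68 against 126 ± 43.1 CPM, with 0 higher and 0 lower called adjusted over the list alone. The adjusted p of this list was 0.0754 without replicate 1 of ethanol alone and 0.124 without replicate 1 of the gavage group.

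Enzymes of ethanol and acetaldehyde metabolism shifted down, with 10 of 12 members lower (median -0.64, adjusted p = 0.00109). The adjusted p was 0.587 with an estimated correlation. Cyp2e1, the ethanol-oxidising cytochrome P450 and the most abundant member of this and the pericentral list, stood at 2988 ± 602 against 7546 ± 1883 CPM (log2 fold change -1.34, SE 0.32, edgeR adjusted p = 0.163). Adh1, the main hepatic alcohol dehydrogenase, stood at 1526 ± 371 against 2424 ± 33.8 CPM (edgeR adjusted p = 0.276), and Aldh2, the mitochondrial aldehyde dehydrogenase, at 1859 ± 42.7 against 2329 ± 198 CPM (edgeR adjusted p = 0.487). Singled out after their values were seen, Adh4 stood at 24.5 ± 3.58 against 121 ± 55.4 CPM and Cat, the peroxisomal catalase, at 1252 ± 124 against 2998 ± 199.6 CPM. Adjusted over the list alone, 1 higher and 3 lower were called. Pericentral hepatocyte markers shifted down with 8 of 12 lower (median -0.30, adjusted p = 0.0459). That adjusted p was 0.668 with an estimated correlation. Periportal markers shifted down with 11 of 12 lower (median -0.69, adjusted p = 3.39e-04). With an estimated correlation, the adjusted p was 0.791. Pck1, the gluconeogenic enzyme and most abundant periportal member, stood at 1351 ± 307 against 3257 ± 1317 CPM. Rgn, a pericentral marker singled out after its value was seen, stood at 585 ± 41.3 against 1527 ± 456 CPM. Adjusted over the list alone, the counts higher and lower were 1 and 3 for pericentral and 0 and 1 for periportal markers. The pericentral call was lost without replicate 2 of ethanol alone (adjusted p = 0.137) and without replicate 1 of the gavage group (adjusted p = 0.152). It was also lost with the stricter filter (adjusted p = 0.06) and without shared genes (adjusted p = 0.261).

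Genes of cholesterol synthesis and uptake shifted down, with 20 of 24 lower (median -0.57, adjusted p = 8.62e-04). An estimated correlation gave an adjusted p of 0.791. Insig1, a sterol-regulated retention protein singled out after its value was seen, stood at 95.1 ± 30.2 against 305 ± 38.3 CPM. Genes of fatty acid and triglyceride synthesis shifted up with 12 of 20 higher (median 0.49, adjusted p = 0.0417). The adjusted p was 0.791 with an estimated correlation. Replicate 1 of the gavage group stood apart in this list. Scd1, the stearoyl-CoA desaturase, had 34079 and 4689.9 CPM in the gavage libraries against 8667 and 9265 CPM. Fasn, the fatty acid synthase, singled out after its values were seen, had 5245 and 1572 against 583 and 1173 CPM. The list was lost without that library (adjusted p = 0.497), where Scd1 had a log2 fold change of -0.93. It was also lost without replicate 1 (adjusted p = 0.127) or replicate 2 (adjusted p = 0.434) of ethanol alone. The same held with library totals in place of a composition factor (adjusted p = 0.0596), no filter (adjusted p = 0.0543) or the stricter filter (adjusted p = 0.0571). Srebf1, a transcription factor of lipid synthesis, stood at 152 ± 16.2 against 219 ± 95.6 CPM (edgeR adjusted p = 0.452). The summed adipose markers were higher in both libraries numbered 1, at 123 CPM against 19.3 CPM in replicate 2 within the gavage group and at 78.2 against 13.7 CPM within ethanol alone. Within ethanol alone, Scd1 and Fasn were not higher in replicate 1 than in replicate 2, so there they did not go with these markers. Cholesterol synthesis lost its call without replicate 1 of the gavage group (adjusted p = 0.152). Adjusted over the list alone, the counts higher and lower were 0 and 0 for cholesterol and 0 and 0 for fatty acid synthesis.

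Genes of bile acid synthesis and transport shifted down, with 13 of 19 lower (median -0.50, adjusted p = 0.0229). With an estimated correlation, their adjusted p was 0.597, and 1 higher and 1 lower were called adjusted over the list alone. Slco1b2, an uptake transporter and the most abundant member, stood at 871 ± 87.2 against 1558 ± 113 CPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, lay in the other direction, at 299 ± 81.6 against 95.4 ± 26.3 CPM (log2 fold change 1.65, SE 0.32, edgeR adjusted p = 0.136). Nr0b2, a nuclear receptor that represses it, was singled out after its value was seen and stood at 12.5 ± 0.939 against 44.2 ± 9.22 CPM. The list holds Slco1a1, which stood at 629 CPM in replicate 1 of ethanol alone and at 10.1, 8.73 and 1.86 CPM in the other libraries. With replicate 1 of ethanol alone left out, the list still pointed down. The call was lost without replicate 1 of the gavage group (adjusted p = 0.152). Genes of amino acid catabolism and the urea cycle shifted down with 13 of 16 lower (median -0.54, adjusted p = 0.013). With an estimated correlation the adjusted p was 0.791, with 0 higher and 0 lower called adjusted over the list alone. Cps1, the entry enzyme of the urea cycle, stood at 5092 ± 2345 against 5026 ± 1499 CPM. Otc, singled out after its value was seen, stood at 325 ± 91.4 against 593 ± 43 CPM. This call was lost without replicate 1 of the gavage group (adjusted p = 0.497) and without genes that also stand in another list (adjusted p = 0.0793).

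**Figure D2:**
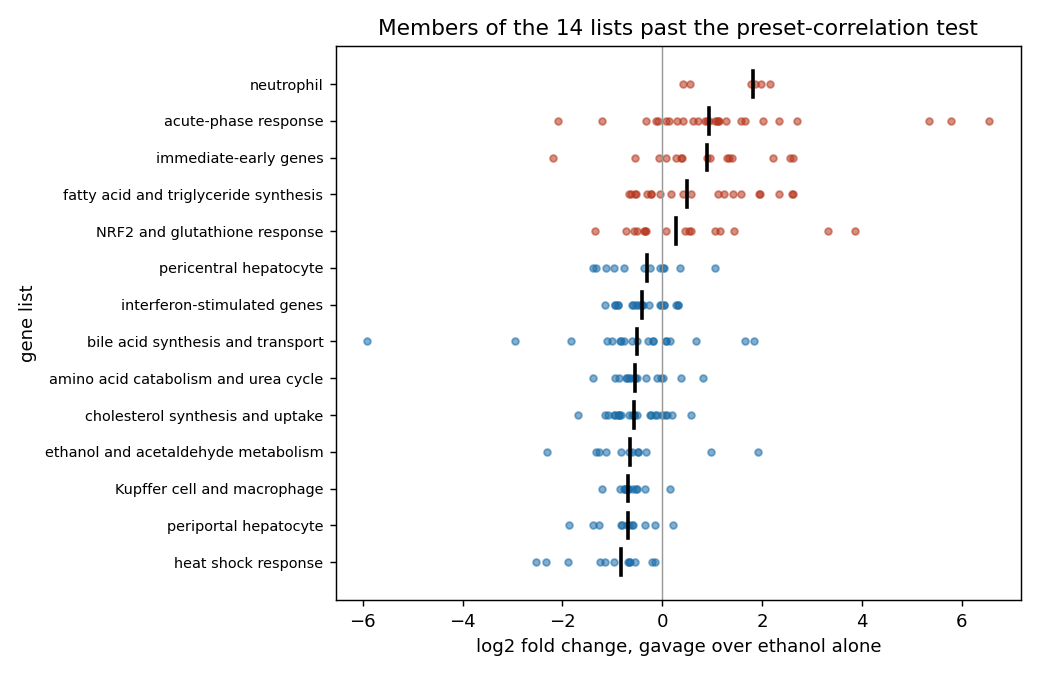
Log2 fold change of gavage over ethanol alone for each tested member (points) and the median (black bar) of the 14 gene lists past an adjusted p of 0.05 in camera with a preset correlation; red lists shifted up and blue lists down. The medians run from -0.83 for heat shock to 1.82 for neutrophil markers. No list passed with an estimated correlation (smallest adjusted p = 0.587), a test on 2 residual degrees of freedom.

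Of the 36 lists tested, 14 passed in camera with the preset correlation, 5 up and 9 down, and 22 did not. The estimated correlation lay under the preset 0.01 for Kupffer cell, immediate-early, bile acid and pericentral lists (0.0042, -0.043, -0.032 and -0.061). That test had 2 residual degrees of freedom, so losing these 4 calls there does not show correlated members. For the cholesterol, NRF2, periportal, fatty acid and amino acid lists the estimate ran from 0.359 to 0.577. PPARa targets and fatty acid oxidation had 18 of 27 members lower (adjusted p = 0.0694). Cpt1a, the carnitine palmitoyltransferase, stood at 433 ± 205 against 419 ± 74.7 CPM (edgeR adjusted p = 0.959). Fgf21, a hepatic hormone, stood at 7.28 ± 5.25 against 4.43 ± 1.5 CPM (edgeR adjusted p = 0.538). Gluconeogenesis and glucose handling had 9 of 16 members lower (adjusted p = 0.375). The list of methionine and one-carbon metabolism (adjusted p = 0.37), with 9 of 14 members lower, held Mat1a at 7329 ± 1857 against 4452 ± 1591 CPM. Circadian clock genes (adjusted p = 0.113) held Bhlhe40 at 199 ± 0.435 against 132 ± 12.5 CPM and Nfil3 at 18.7 ± 0.154 against 37 ± 7.7 CPM (edgeR adjusted p = 0.142). Chemokines and NF-kB targets (adjusted p = 0.729), with 9 of 15 members higher, held Nfkbia at 27.4 ± 6.63 against 68.8 ± 24.4 CPM. Glucocorticoid-responsive genes (adjusted p = 0.437) held Tat at 866 ± 358 against 2063 ± 367 CPM. The p53 target list (adjusted p = 0.729) held Trp53inp1 at 164 ± 43.5 against 135 ± 1.56 CPM. The list of autophagy and lysosome (adjusted p = 0.729), with 12 of 19 members lower, held Ctsl at 1417 ± 186 against 728 ± 106 CPM. That of the cell cycle (adjusted p = 0.0694), with 12 of 15 members lower, held Ccnd1 at 238 ± 93.6 against 146 ± 78.7 CPM. The unfolded protein and integrated stress response (adjusted p = 0.782) held Hspa5 at 1433 ± 220.1 against 1378 ± 573 CPM. Its median was -0.041, its mean 0.20 and the direction of its test down. For the xenobiotic-responsive P450 list (adjusted p = 0.81), with Cyp2c29 at 1648 ± 263 against 1575 ± 1332 CPM, the median of 0.088 and the mean of 0.058 lay above 0 and the test pointed down. The counts called higher and lower adjusted over the list alone were 0 and 2 for PPARa targets, 1 and 1 for glucose handling, 2 and 2 for one-carbon metabolism, 2 and 4 for the clock, 1 and 2 for chemokines. They were 1 and 2 for glucocorticoid-responsive genes, 0 and 1 for p53 targets, 0 and 0 for autophagy, 0 and 0 for cell cycle, 0 and 1 for the unfolded protein response and 0 and 0 for the P450 list. Some of these lists passed with a library left out. Without replicate 1 of ethanol alone, the lists of one-carbon metabolism (adjusted p = 0.0391), P450 genes (adjusted p = 0.031) and the cell cycle (adjusted p = 0.0151) shifted down. The clock list shifted up without replicate 2 of ethanol alone (adjusted p = 0.034) and the unfolded protein list without replicate 1 of the gavage group (adjusted p = 0.0344). PPARa targets shifted down without replicate 2 of the gavage group (adjusted p = 2.28e-04) and with no filter (adjusted p = 0.0277), as did the cell cycle list with no filter (adjusted p = 0.0277).

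Among cell type markers, the secretory and identity genes of hepatocytes did not pass (adjusted p = 0.109), with Alb, albumin, at 91546 ± 11695 against 105882 ± 7094 CPM. Sinusoidal endothelial markers (adjusted p = 0.444) held Eng at 98.5 ± 4.62 against 104 ± 4.21 CPM. Stellate cell and fibroblast markers (adjusted p = 0.81) held Dcn at 245 ± 16.2 against 242 ± 36.8 CPM. Monocyte markers (adjusted p = 0.514) held Lyz2 at 53.8 ± 2.38 against 69.5 ± 7.84 CPM. T and NK cell markers (adjusted p = 0.192) held Lck at 1.04 ± 0.107 against 1.8 ± 0.671 CPM. B and plasma cell markers (adjusted p = 0.756), with 7 of 8 members lower, held Xbp1 at 341 ± 13.5 against 214 ± 18.5 CPM. Cholangiocyte markers (adjusted p = 0.669) held Spp1 at 51.1 ± 12.3 against 57.1 ± 4.73 CPM. Erythroid markers (adjusted p = 0.079) held Hbb-bs at 49.7 ± 10.1 against 73.8 ± 26.2 CPM. Mitochondrially encoded genes (adjusted p = 0.706) held mt-Cytb at 10527 ± 352 against 10796 ± 1088 CPM, and the sign of its fold change differed when library totals replaced the composition factor. The called counts, higher and lower, adjusted over the list alone were 0 and 0 for hepatocyte, 1 and 1 for endothelial, 0 and 0 for stellate, 0 and 0 for monocyte. They were 0 and 0 for T and NK, 0 and 0 for B and plasma, 0 and 0 for cholangiocyte, 0 and 0 for erythroid and 0 and 0 for mitochondrial genes. The hepatocyte list shifted down without replicate 2 of ethanol alone (adjusted p = 0.0334), without replicate 2 of the gavage group (adjusted p = 0.0273) and with no filter (adjusted p = 0.0427). Erythroid markers shifted down without replicate 2 of ethanol alone (adjusted p = 0.00327) and without replicate 1 of the gavage group (adjusted p = 0.0233). B and plasma cell markers shifted down without replicate 1 of the gavage group (adjusted p = 0.0272).

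Principal components, the axes of largest spread between libraries, were computed on log2 CPM. Component 1 (49.9% of the variance) separated the libraries numbered 1 from those numbered 2, and component 2 (40.3%) separated the groups. The most alike pair crossed the groups, replicate 2 of ethanol alone and replicate 2 of the gavage group (r = 0.974). Within groups r was 0.954 for ethanol alone and 0.952 for gavage. Single libraries stood apart from the rest of their group. Pancreas markers, none of which entered the test, summed to 1241 CPM in replicate 1 of ethanol alone, with Pnlip, pancreatic lipase, at 249 CPM, and to 0.264, 0.127 and 0.465 CPM in the other libraries. With no filter the pancreas list was tested and shifted down (adjusted p = 0.0012). It also did so without replicate 2 of ethanol alone (adjusted p = 3.01e-22) and without replicate 1 (adjusted p = 3.41e-04) or replicate 2 (adjusted p = 1.93e-04) of the gavage group. Adipose markers (adjusted p = 0.706) were higher in replicate 1 of both groups, with Fabp4 at 54.8 CPM in replicate 1 and 12.1 CPM in replicate 2 of the gavage group and at 27.4 and 7.93 CPM in those of ethanol alone. This list shifted up without replicate 1 of ethanol alone (adjusted p = 0.0173) or replicate 2 of the gavage group (adjusted p = 7.02e-04) and down without replicate 1 of the gavage group (adjusted p = 0.0325). Male- and female-biased liver genes (adjusted p = 0.833; median 0.22, mean -0.93, test direction down) separated replicate 1 of ethanol alone, where Cyp2a4, the most abundant member, stood at 69.6 CPM against 511, 1382 and 741 CPM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 1, 1, 1 and 0 counts in the 4 libraries, each under the floor of 3 counts. DESeq2, which called 1177 genes in the 4 libraries, called 377 without replicate 1 and 1290 without replicate 2 of ethanol alone. It called 244 without replicate 1 and 513 without replicate 2 of the gavage group, in fits chosen after seeing the data.

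**Figure D3:**
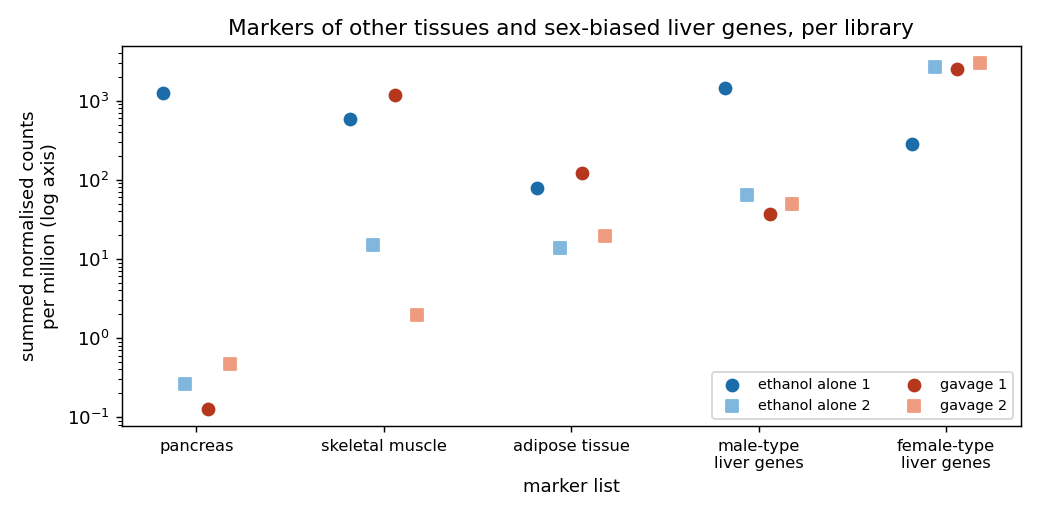
Summed CPM, on a log axis, of markers of pancreas, skeletal muscle and adipose tissue and of male-type and female-type liver genes, one point per library (circles replicate 1, squares replicate 2; blue ethanol alone, red gavage). Muscle and adipose markers are higher in both libraries numbered 1, and pancreas and male-type markers in replicate 1 of ethanol alone, at 1241 and 1466 CPM.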

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

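Alternatives other than those in the second paragraph and those with the offset were fixed before the data were examined, and in the last paragraph the splits, the correlations without marker genes and without the length trend, and the bootstrap interval were chosen after the result was seen. The count of 0 genes held with DESeq2 size factors, upper-quartile factors, library totals, no filter, the stricter filter and limma-voom. The likelihood-ratio test called 549 (285 higher, 264 lower, 489 at least 2-fold) and DESeq2 1177 (525 higher, 652 lower, 651 at least 2-fold); the cause was not tested. The count of lists, 14, became 0 with an estimated correlation and 0 with fry for one direction (smallest adjusted p = 0.150), while fry called 9 for change in either direction, and lay between 11 and 17 under the other planned settings with all libraries. Those 9 were the acute-phase, immediate-early, NRF2 and Kupffer cell lists and, not past camera, those of chemokines, the unfolded protein response, p53 targets, the clock and autophagy. The pancreas list, not tested in the count of 14, is among the 17 with no filter. With a single library left in a group, that library is assumed to vary like the other group. Without each library in turn, the count of genes ranged from 0 to 31, higher from 0 to 31, lower from 0 to 10 and at least 2-fold from 0 to 31, and the count of lists from 12 to 18, the pancreas list among them except without replicate 1 of ethanol alone; 12 genes were called without replicate 2 of ethanol alone and 31 without replicate 2 of the gavage group.

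Among alternatives chosen after seeing the data, the offset for length and GC content gave 3 (3 higher, 0 lower, 3 at least 2-fold) genes and DESeq2 with it 924 (403 higher, 521 lower, 566 at least 2-fold). A robust fit gave 28 (19 higher, 9 lower, 28 at least 2-fold), bias-adjusted deviances 4 (4 higher, 0 lower, 4 at least 2-fold) and leaving out marker genes 3 (3 higher, 0 lower, 3 at least 2-fold). DESeq2 gave 377 (190 higher, 187 lower, 311 at least 2-fold) without replicate 1 of ethanol alone, 1290 (611 higher, 679 lower, 939 at least 2-fold) without its replicate 2, 244 (119 higher, 125 lower, 244 at least 2-fold) without replicate 1 of the gavage group and 513 (233 higher, 280 lower, 513 at least 2-fold) without its replicate 2. The cause was not tested.

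Of 1610 values of the 124 genes with alternatives, 1385 kept direction and side of the threshold under planned settings, 199 passed the threshold and 26 changed sign; under added settings 797, 407 and 33 of 1237 did. The sign changes were in 13 genes, and 0 of them passed the threshold. With upper-quartile factors the other sign was seen for Cpt1a -0.0049, Cps1 -0.023 and Dcn -0.019. With limma-voom the other sign was seen for Cpt1a -0.028 and Cps1 -0.025. With library totals the other sign was seen for Eng 0.0024 and mt-Cytb 0.037. With the offset the other sign was seen for Cpt1a -0.039, Cps1 -0.14, Hspa5 -0.011, Dcn -0.092, Spp1 0.0039 and mt-Cytb 0.17. With DESeq2 and the offset the other sign was seen for Cpt1a -0.044, Cps1 -0.14, Hspa5 -0.014, Dcn -0.096, Spp1 0.00053 and mt-Cytb 0.17. With DESeq2 without replicate 1 of ethanol alone the other sign was seen for Cps1 -0.27, Hspa5 -0.33 and Cyp2c29 -0.62. With DESeq2 without replicate 2 of ethanol alone the other sign was seen for Cpt1a -0.13, Dcn -0.14, mt-Cytb 0.061 and Glyctk 0.055. With DESeq2 without replicate 1 of the gavage group the other sign was seen for Scd1 -0.93, Dcn -0.050 and Fabp4 -0.55. With DESeq2 without replicate 2 of the gavage group the other sign was seen for Fgf21 -0.34, Cpt1a -0.56, Cps1 -0.57, Hspa5 -0.13, Cyp2c29 -0.13, Trp53inp1 -0.044 and Spp1 0.042. Without each library in turn, log2 fold changes ranged as follows: Fgf21 -0.32 to 1.31, Cpt1a -0.55 to 0.46, Scd1 -0.93 to 1.92, Cps1 -0.56 to 0.43, Hspa5 -0.34 to 0.50, Cyp2c29 -0.64 to 1.32, Trp53inp1 -0.027 to 0.53, Dcn -0.18 to 0.16, Spp1 -0.43 to 0.059, Fabp4 -0.54 to 2.06, mt-Cytb -0.16 to 0.015 and Glyctk -0.53 to 0.0068. The cause was not tested.

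With the offset, the pericentral list lost its call (adjusted p = 0.0459 before and 0.0969 after), with a median log2 fold change of -0.30 (quartiles -1.01 and 0.028) before and -0.35 (-0.93 and 0.041) after. The list was near the threshold, and its mean moved from -0.40 to -0.37 while that of the other genes, against which camera tests it, moved from 0.029 to 0.0069. The cell cycle list passed (adjusted p = 0.0482). Lists that did not pass pointed the other way in some settings, with adjusted p by camera of unfolded protein and integrated stress response 0.818, xenobiotic-responsive P450 and conjugation genes 0.973, mitochondrially encoded genes 0.723 and male- and female-biased liver genes 0.999 with the offset, B and plasma cell 0.945 with the stricter filter, and glucocorticoid-responsive genes 0.944, autophagy and lysosome 0.912, B and plasma cell 0.623 and cholangiocyte 0.808 with the offset and without replicate 1 of ethanol alone. Without each library in turn, the adjusted p of lists whose direction changed ranged as follows: chemokines, cytokines and NF-kB targets 0.362 to 0.859, PPARa targets and fatty acid oxidation 2.28e-04 to 0.856, unfolded protein and integrated stress response 0.0344 to 0.665, xenobiotic-responsive P450 and conjugation genes 0.031 to 0.156, glucocorticoid-responsive genes 0.069 to 0.856, autophagy and lysosome 0.186 to 0.945, B and plasma cell 0.0272 to 0.594, hepatic stellate cell and fibroblast 0.138 to 0.665, cholangiocyte 0.372 to 0.906, adipose tissue 7.02e-04 to 0.665 and mitochondrially encoded genes 0.127 to 0.925. Past the threshold the unfolded protein list pointed up and the adipose list down (adjusted p = 0.0325) without replicate 1 of the gavage group. The cause was not tested.

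Same-numbered libraries share a replicate number and neighbouring places in the running numbers of the library names, and no label says what either marks. With that number as a replicate block, edgeR's quasi-likelihood test called 410 (238 higher, 172 lower, 396 at least 2-fold) genes, and with the offset as well 1009 (520 higher, 489 lower, 673 at least 2-fold); in simulated counts the block gave 44 false calls against 15 without it. The 16 genes of smallest p, which had been chosen on the same libraries, were all called with the block. With the block, 12 lists passed. Among them were the cell cycle and erythroid lists (adjusted p = 0.0459 for both). The lists of fatty acid synthesis (0.0857), bile acids (0.0551), NRF2 (0.0548) and pericentral markers (0.0857) no longer passed. Log2 fold changes of the other sign were Cpt1a -0.028 and Cps1 -0.029 with the block and Cpt1a -0.13, Cps1 -0.21, Dcn -0.084 and mt-Cytb 0.18 with block and offset, and the lists pointing the other way were xenobiotic-responsive P450 and conjugation genes 0.973 and male- and female-biased liver genes 0.973 (adjusted p). Deviations of same-numbered libraries from their group means correlated across genes at r = 0.587, at r = 0.562 without marker genes and at r = 0.596 once the trend in length and GC content was removed, which argues against that trend as the cause. Genes are not independent replicates. Over 168 members of the metabolic lists r was 0.396, with a 95% bootstrap interval over genes of 0.177 to 0.585. The bound against attached tissue had been set at 0.3 before r was seen, and the interval was added after it was seen; as it includes that bound, attached tissue stays open for these genes. The 4 libraries make 3 splits, too few for a share under 0.05. The real split gave 2497 genes at an unadjusted p under 0.05, 1 of 3 with as many, and the highest other, between the replicate numbers, 704. DESeq2 called 1177 genes for the real split, 263 between the replicate numbers and 1 for the remaining split.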

Other observations

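The gene groups in the first paragraphs and the tests in the patterns were chosen after the values were seen, except that the estimated correlation was planned as an alternative and that the bounds for a length trend on gene lists were set before the lists were tested with the offset, itself added after the data had been examined. No single gene named here passed edgeR's quasi-likelihood test in the main fit, which has no replicate block. Psat1 belongs to a list of 7 enzymes of serine synthesis and mitochondrial folate metabolism, which summed to 207 and 192 CPM in the gavage libraries against 211 and 225 CPM. Shmt2, its most abundant member, stood at 142 ± 2.96 against 207 ± 9.29 CPM. The members Mthfd1l and Mthfd2 stood at 6.44 ± 1.03 against 0.891 ± 0.328 CPM and at 18.1 ± 11.3 against 2.09 ± 0.201 CPM (edgeR adjusted p = 0.12 and 0.133). Psph, the last enzyme of serine synthesis, stood at 10.5 ± 0.451 against 6.24 ± 0.185 CPM. Asns, asparagine synthetase, which is not in that list, stood at 10.8 ± 2.94 against 1.39 ± 1.35 CPM. Khk, ketohexokinase, stood at 699.7 ± 197 against 390.0 ± 43.7 CPM and Tkfc, the triokinase, at 2209 ± 522 against 362 ± 106 CPM (edgeR adjusted p = 0.12). The fructose transporter Slc2a5 stood at 7.53 ± 1.33 against 3.05 ± 0.122 CPM and Glyctk, glycerate kinase, at 237 ± 52 against 281 ± 76.6 CPM.

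Osmr, the oncostatin M receptor, stood at 17.9 ± 1.08 against 6.01 ± 0.473 CPM (edgeR adjusted p = 0.108). Il6st stood at 382 ± 31.6 against 233 ± 32.9 CPM and the secreted protein Lrg1 at 1017 ± 53.3 against 241 ± 67 CPM. The chemokine Cxcl1 stood at 50.6 ± 28.3 against 2.78 ± 0.78 CPM. A list of 8 genes of the growth hormone axis summed to 842 and 1171 CPM in the gavage libraries against 2109 and 1579 CPM. Of these, the receptor Ghr stood at 333 ± 11.3 against 644 ± 74.7 CPM and Igf1 at 493 ± 198 against 867 ± 259 CPM. Igfals, which carries IGF1 in plasma, stood at 39.2 ± 16.4 against 144 ± 11.5 CPM. Cish lay the other way, at 23.1 ± 2.39 against 8.8 ± 4.74 CPM. The clock list did not pass in camera (adjusted p = 0.113) and passed in fry for change in either direction (adjusted p = 0.0373). Of its members, Arntl stood at 7.86 ± 0.579 against 22.5 ± 7.13 CPM and Npas2 at 1.52 ± 0.552 against 7.29 ± 4.31 CPM. Per3 stood at 58.2 ± 0.31 against 9.13 ± 5.35 CPM. The time of killing is not given for the mice without a binge.

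Replicate 1 of ethanol alone carried male-type liver transcripts, summing to 1466 CPM against 64.8, 36.7 and 49.3 CPM in the other libraries. Its summed Y-linked count of 1 had an upper limit of 0.0583% of the counts of their X-linked partners, which argues against the liver of an animal with a Y chromosome. Its female-type genes lay below the lowest other library by a median of 17.4-fold, but dilution by RNA of other tissues would lower all liver transcripts alike, and for the 15 hepatocyte secretory and identity genes, a list fixed beforehand, that fold had a median of 0.715 and reached at most 1.05. The other library of its group lay lower by a median log2 ratio of 5.56 over the male-type genes, but these were chosen for the pattern, so this does not test the group as an explanation. A wrong label or a hormonal difference between animals was not tested and stays open.

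Muscle and adipose transcripts were higher in replicate 1 of both groups, with summed muscle markers at 1182 CPM against 1.96 CPM in replicate 2 within the gavage group and at 588 against 15.2 CPM within ethanol alone. Carry-over of RNA from ethanol alone into the gavage group would bring pancreas transcripts too, but these reached 0.0103% in replicate 1 of the gavage group of their level in replicate 1 of ethanol alone. Carry-over the other way would bring Saa1, Saa2 and Lcn2, the 3 acute-phase members at least 10-fold higher in replicate 1 of the gavage group than in replicate 2 of ethanol alone, at about the 49.7% that muscle markers reached, but their sum reached 0.678%. Tissue attached to the liver piece stays open, since the 8 of 8 adipose markers higher there in both groups are part of the pattern and do not test it. No biological explanation was tested; the running numbers in the library names place replicate 1 of both groups before replicate 2 without saying what they mark, so an order of handling was not tested and stays open.

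Fold changes after gavage followed transcript length, with a rank correlation of 0.320 across 13110 genes, which are not independent, and of 0.164 when the gavage mean was set against replicate 2 of ethanol alone; it was 0.376 between the libraries of ethanol alone and 0.0287 between those of the gavage group. With an offset removing the trend in length and GC content, camera with the preset correlation gave an adjusted p of 2.97e-16 for the acute-phase list, 5.99e-07 for heat shock and 0.00126 for Kupffer cell markers, with 105%, 92.6% and 69.1% of their medians left. The trend is therefore not the whole of the shifts of these 3 lists, while over the 14 lists the share of the median left ran from 49.7% for NRF2 to 136% for bile acids. When the correlation between members was estimated, the adjusted p was 0.587 for the acute-phase, heat shock and Kupffer cell lists alike. Correlation between members stays open for the acute-phase list, since lists planted in simulated counts also failed that test. The binge itself stays open as a biological explanation, and the 14 lists were tested on 2 libraries per group.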
